A study of Mus musculus with 7 samples.

How the data were processed

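RNA from 7 leukemic cell suspensions of terminally ill C57Bl/6 mice was measured on Affymetrix mouse expression arrays, 1 array per suspension. Per the labels, 3 arrays held bone marrow cells of mice with leukemia driven by activated NOTCH1 (ICN1) and 4 held thymus cells of mice with leukemia driven by the TEL-JAK2 fusion kinase. The tissues were crushed or dissociated in cold buffer, filtered and lysed after centrifugation, and no sorting step is named in the labels. Each genotype was sampled from 1 tissue, so genotype and tissue enter every comparison as 1 term. Replicates were numbered in accession order, and the number only names an array. The sample titles carry different identifiers for the arrays of a group but do not state outright that these are separate animals, and p-values measure the spread between these samples.

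The authors deposited 1 table of log2 expression values, 1 value per probe set and array, which the submitters' processing notes credit to RMA, a method that corrects background, normalizes across arrays and summarizes the probes of a probe set. The RMA version and its settings are not given in the sources used here. The range of the values (2.57 to 14.86), together with array medians between 5.4 and 5.5, fits a log2 scale, and no further transformation or normalization was applied. RMA draws all arrays toward 1 distribution, so a difference in total RNA between the leukemias cannot be read from these values. It also compresses folds when the lower group lies near background. Detection calls and scan dates were not used here, so no probe set was called present or absent and batches could not be tested. The number of arrays limits the precision. No column of per-sample values was left unused.

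Probe sets were named through the platform annotation supplied with the table. Of 45037 probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none. Of those with 1 symbol, 34741 were matched in a RefSeq gene table of assembly GRCm38.p6, which updated 0 symbols and was used for names and chromosome membership only. Each gene was represented by its probe set with the highest mean over the 7 arrays, among probe sets with 1 symbol, which gave 18193 genes, 9010 of them with more than 1 probe set. The table contained 0 Affymetrix control probe sets.

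Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, two-sided), as TEL-JAK2 minus ICN1. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 18193 genes. Differences are on the log2 scale, given with the standard error (SE) of the fit. The folds beside them are 2 to the power of the difference. Gene lists, 29 tested of 30 fixed, were compared with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the lists, and again with an estimated correlation and with fry. The list of sex-linked genes was given as values only. The result of 1 tested list is not reported here, though the list remains in the counts of lists. Some fixed members had no probe set with 1 symbol in the annotation used here and were not analysed here. The genes of each of 20 chromosomes were tested in the same way as the lists.

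The test, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named Notch1, Jak2 and Etv6, the 12 largest differences per direction among called genes whose groups did not overlap, up to 4 called members of each list with the smallest adjusted p, up to 2 members with the largest adjusted p, the 3 brightest members of each list of other cell types, and the members of any count of 5 or fewer. Hes1, Myc, Gzmb and Ifng were named after their values were seen. The alternatives were all probe sets tested singly, the mean of a gene's probe sets, no cross-hybridizing probe sets, no dim genes, 3 other scalings (quantile normalization applied again, median centring, cyclic loess), a variance trend with robust moderation, array weights, a test against a 1.5-fold difference, a per-gene test with unequal variances, an adjusted p under 0.01, and each array left out in turn. The linear-scale offset planned for untransformed values was not needed. An array scaling on the mean of the CD3 genes Cd3d, Cd3e, Cd3g and Cd247, and a fit without ICN1 replicates 1 and 2, were added after seeing the data.

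The scripts were tested on simulated arrays of all 18193 genes. With 200 changed genes, the fit recovered 64 of 100 genes changed by 1 log2 and 92 of 100 changed by 2 log2, and called 7 unchanged genes. With no gene changed it called 0. Among 400 simulated lists without a shift, 19 had a camera p under 0.05 when genes varied independently. Figures were drawn with matplotlib 3.10.9.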

Results

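The transcriptomes of 2 mouse models of T-cell acute lymphoblastic leukemia were compared. One was driven by ICN1, the activated intracellular part of the receptor NOTCH1, and the other by TEL-JAK2, a fusion that makes the kinase JAK2 constitutively active. The series held 3 ICN1 arrays from leukemic bone marrow and 4 TEL-JAK2 arrays from leukemic thymus. Array medians lay between 5.4 and 5.5 on the log2 scale. Pearson's r over 45037 probe sets was 0.973 to 0.982 between ICN1 arrays, 0.975 to 0.989 between TEL-JAK2 arrays and 0.921 to 0.944 between the groups. The first principal component held 68.2% of the variance. The closest 2 arrays, TEL-JAK2 replicates 1 and 3, differed more than 2-fold in 846 probe sets. Differences are TEL-JAK2 minus ICN1 with the SE, for n = 3 ICN1 and n = 4 TEL-JAK2 arrays.

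The question posed by the series is how the 2 leukemias differ in gene expression. The 12 genes with the largest differences in favour of TEL-JAK2, among called genes whose groups did not overlap, included Myl10, a myosin light chain gene (454-fold, log2 difference 8.83 ± 0.17), Drc1, a component of motile cilia (264-fold, 8.05 ± 0.23), and Gldc, the glycine decarboxylase of the glycine cleavage system (72.0-fold, 6.17 ± 0.11). Also among the 12 were Epcam, an epithelial adhesion molecule (6.15 ± 0.48), Enah, a regulator of actin filaments (6.06 ± 0.19), and Socs2, a feedback inhibitor of cytokine signalling (5.61 ± 0.37). The ICN1 means of these 6 genes lay between 3.73 and 5.75, near background, where RMA compresses folds. The 12 genes with the largest differences in the opposite direction were led by genes of red blood cells and their precursors. They included Slc4a1, the anion exchanger of the red cell membrane (-8.77 ± 0.30), Rhag (-8.60 ± 0.14), the carbonic anhydrases Car2 (-7.65 ± 0.20) and Car1 (-7.06 ± 0.21), and Klf1, an erythroid transcription factor (-6.59 ± 0.22). The TEL-JAK2 means of these 5 genes lay between 3.30 and 5.89, again below or near the array medians, so the same limit holds. Absence of overlap between the 2 groups was a condition for choosing these genes in both directions.

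In total 4380 of 18193 genes (24.1%) were called by limma, 2165 higher and 2215 lower in TEL-JAK2, and 2078 of them differed at least 2-fold (969 higher, 1109 lower). The groups did not overlap in 6234 genes (34.3%), where chance gives 5.71%. A test against a 1.5-fold difference called 1187 genes and a per-gene test with unequal variances 1632. A fit without ICN1 replicates 1 and 2, which held both Xist and Y-linked transcripts, leaves 1 ICN1 array and so no spread within ICN1. The direction split rests on the authors' scaling. Centring each array on the mean of 4 CD3 genes was chosen after seeing the data. It moved every difference by -0.62 and the median gene to -0.58, and left 787 genes higher and 11410 lower (6.45% of calls higher, against 49.4%). Genes near background in both groups moved as well. Il2, at 3.91 in ICN1 and 3.89 in TEL-JAK2, was then called lower (-0.63, adjusted p = 0.0254 by limma). The count of lower genes with this centring therefore includes such genes, and counts for single lists can include them too.

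**Figure D1:**
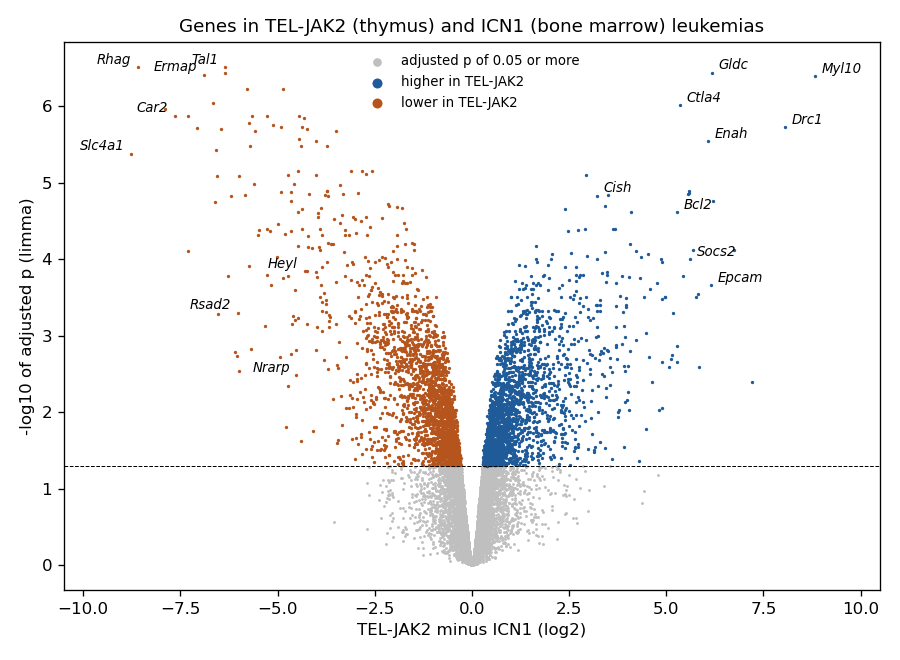
Each point is 1 of 18193 genes, with the log2 difference TEL-JAK2 minus ICN1 on the horizontal axis and the negative log10 of limma's adjusted p on the vertical axis, and the dashed line marks an adjusted p of 0.05. With the deposited scaling 2165 genes lay higher and 2215 lower in TEL-JAK2, with Myl10 (8.83) and Slc4a1 (-8.77) at the ends. With CD3 centring the counts were 787 and 11410, the latter including genes near background in both groups.

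Markers of cells other than T cells differed for some cell types. Of 11 measured erythroid genes, 9 were lower in TEL-JAK2 and 2 were not called (Gata1 at -0.81 ± 0.26 and Hba-a1, whose probe set averaged 3.91 in ICN1 and 3.87 in TEL-JAK2). The mean level of the list was 11.05 to 11.33 in the ICN1 arrays and 5.45 to 5.93 in the TEL-JAK2 arrays, and 10 members were lower when adjusted over the list alone. Its camera test had an adjusted p = 1.73e-13, and it was the single list whose call held with an estimated correlation (adjusted p = 0.0382). The megakaryocyte and platelet list had 4 of 5 members lower, both over all genes and adjusted over the list alone. The remaining one, Gp1bb, was not called (0.25 ± 0.16). Its other probe set, averaging 4.78, was called lower (-2.36, adjusted p = 0.0409 by limma over all probe sets). Ppbp, a platelet chemokine, differed by -5.67 ± 0.69 and Pf4, another, by -2.24 ± 0.63. The integrin Itga2b (-0.98 ± 0.23) lost its call without TEL-JAK2 replicate 1 (adjusted p = 0.0544). Gp9 (-0.92 ± 0.23) lost it without ICN1 replicates 1 or 2 or TEL-JAK2 replicates 1, 2 or 4 (adjusted p from 0.0561 to 0.0713). The list was called with an adjusted p = 0.0231, and adjusted p = 0.450 with an estimated correlation. Leaving out ICN1 replicate 1 ended the call of Pf4 (adjusted p = 0.0667), as did leaving out TEL-JAK2 replicates 1, 2 or 3 (0.0971, 0.0868 and 0.0885). The list call was lost with dim genes left out (adjusted p = 0.0652). With CD3 centring 11 erythroid genes, among them Hba-a1 with its low values in both groups, and 4 megakaryocyte genes were lower.

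Granulocyte genes were lower for 5 of 14 members and not called for 9, and 8 were lower when adjusted over the list alone. The calprotectin genes S100a9 and S100a8 differed by -3.36 ± 0.58 and -3.17 ± 0.60. Camp (-2.14 ± 0.59) lost its call in 5 of the 7 fits without 1 array, all but those without ICN1 replicates 2 or 3 (adjusted p from 0.0699 to 0.0847). Ngp (-3.08 ± 0.74) lost its call without ICN1 replicate 1 or TEL-JAK2 replicates 1 or 2 (adjusted p = 0.0655, 0.0544 and 0.0547). Lcn2 (-2.27 ± 0.57) lost it without ICN1 replicate 1 or TEL-JAK2 replicates 1, 2 or 3 (adjusted p from 0.0521 to 0.0666). The granulocyte list had an adjusted p = 0.00376 by camera, adjusted p = 0.450 with an estimated correlation, and was not called by fry (adjusted p = 0.054). Monocyte and macrophage genes were lower for 5 of 12 members and not called for 7, and for 6 when adjusted over the list alone. This list had an adjusted p = 0.00173 by camera, adjusted p = 0.450 with an estimated correlation, and was not called by fry (adjusted p = 0.0815). The 5 were Axl (-2.36 ± 0.39, although another, dim probe set with a mean of 3.12 read 0.02), Cd14 (-1.46 ± 0.42), Vcam1 (-4.79 ± 1.05), Mrc1 (-3.45 ± 0.84) and Csf1r (-2.59 ± 0.68). The call of Cd14 was lost in 6 of the 7 fits without 1 array, all but the fit without ICN1 replicate 3 (adjusted p from 0.0566 to 0.128). Calls were lost without ICN1 replicates 1 or 2 for Vcam1 (adjusted p = 0.0508 and 0.0526), Mrc1 (0.0735 and 0.0784) and Csf1r (0.0982 and 0.0956). Leaving out TEL-JAK2 replicate 1 ended those of Mrc1 (0.0614) and Csf1r (0.0792), and leaving out TEL-JAK2 replicate 3 that of Mrc1 (0.0535). Lyz2 (0.31 ± 0.45) and C1qb (-1.86 ± 0.88) were not called. Both lists stood lower in ICN1 replicate 3 (granulocyte 5.96, macrophage 8.54) than in ICN1 replicates 1 and 2 (6.70 and 7.53, 9.91 and 9.65). The TEL-JAK2 levels were 5.03 to 5.83 and 6.23 to 8.43. With CD3 centring 10 granulocyte and 10 macrophage genes were lower. The mean level of the B-lineage list was 6.99, 7.70 and 6.07 in ICN1 replicates 1 to 3 and 6.69 to 7.91 in TEL-JAK2. It was not called (adjusted p = 0.474), and 1 of its 12 members was higher, over all genes and adjusted over the list alone. This was Vpreb1 (2.28 ± 0.53), whose call was lost without ICN1 replicate 1 or TEL-JAK2 replicate 3 (adjusted p = 0.0642 and 0.0505). With CD3 centring 1 B-lineage gene was higher and 2 were lower. Its brightest member, Ighm, read 13.09 ± 0.66 (SD, n = 3) in ICN1 and 12.66 ± 0.92 (SD, n = 4) in TEL-JAK2.

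Among cell types of the thymus, dendritic cell and MHC class II genes had 0 of 12 members called, also when adjusted over the list alone. By camera the list as a whole nevertheless lay higher in TEL-JAK2 (median 1.02, adjusted p = 0.0375, adjusted p = 0.552 with an estimated correlation, and 0.135 by fry). That call was lost without ICN1 replicate 3 (adjusted p = 0.203) and without TEL-JAK2 replicates 1, 2 or 4 (0.0524, 0.0743 and 0.0501), and with dim genes left out (0.0747). Thymic epithelial genes had 3 of 11 members higher, and the same number when adjusted over the list alone. These were Epcam (6.15 ± 0.48), Aire (0.87 ± 0.26) and Foxn1, which turned from 0.33 to -0.29 with CD3 centring. Aire averaged 5.39 in ICN1 and 6.27 in TEL-JAK2. Foxn1 averaged 4.52 and 4.85, near background, and its other probe set was not called (adjusted p = 0.209 by limma over all probe sets). Krt18 (0.18 ± 0.72), Psmb11 (0.04 ± 0.15) and Ccl25 (-0.20 ± 0.22) were not called. The list was not called by camera (adjusted p = 0.0905, but 0.0445 without TEL-JAK2 replicate 3) but was called by fry (adjusted p = 0.00971). The median difference of its members was 0.33, against 6.15 for Epcam. The call of Aire was lost without any 1 of the 3 ICN1 arrays (adjusted p = 0.108, 0.119 and 0.101) and without TEL-JAK2 replicates 1 or 2 (0.0589 and 0.101) and with CD3 centring (0.499), and that of Foxn1 in 6 of the 7 fits without 1 array, all but the fit without TEL-JAK2 replicate 2 (0.0517 to 0.140). Stromal and endothelial genes had 1 of 13 members lower, Pdgfra (-1.52 ± 0.43), and 0 when adjusted over the list alone. Pdgfra lost its call without ICN1 replicates 1 or 2 or TEL-JAK2 replicates 1, 2 or 3 (adjusted p from 0.0963 to 0.126). Its further probe sets were not called (adjusted p = 0.34 and 0.437 by limma over all probe sets). The stromal list was not called (adjusted p = 0.109, but 0.00333 without TEL-JAK2 replicate 4 and 0.0270 without ICN1 replicate 3). With CD3 centring 8 stromal and endothelial genes and 1 dendritic cell gene were lower, and 1 thymic epithelial gene was higher and 3 lower.

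**Figure D2:**
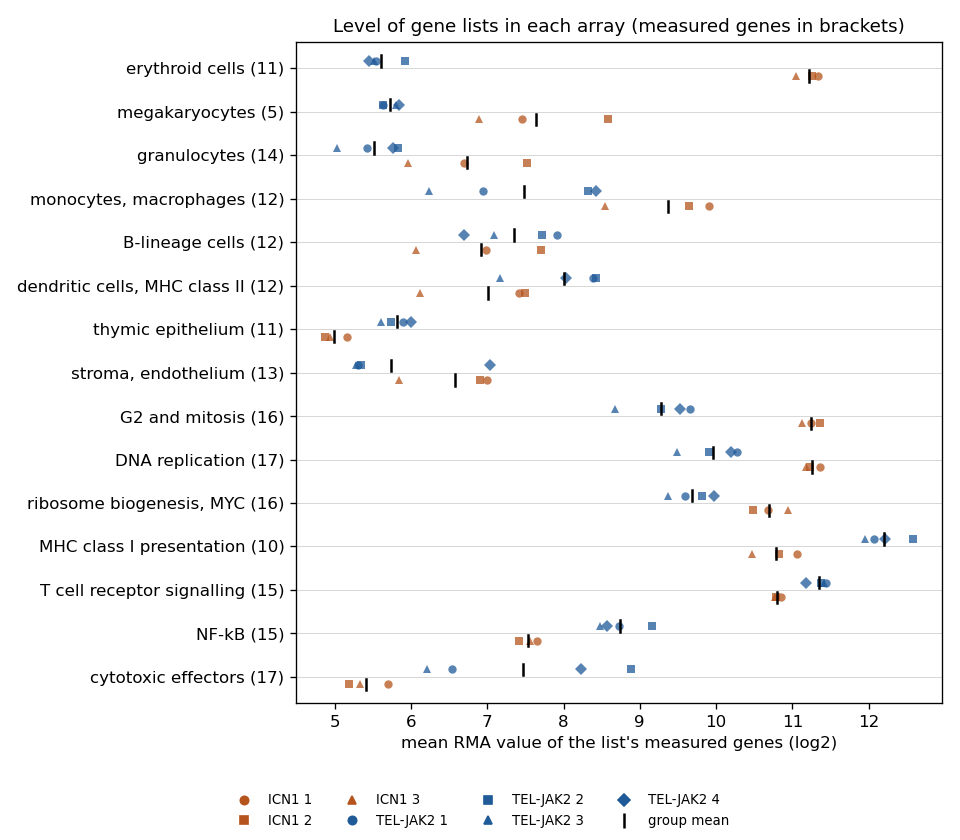
Points give the mean log2 value of each list's measured genes in each of the 7 arrays, black bars the group means, and the number of genes is in brackets. Erythroid levels lie between 11.05 and 11.33 in ICN1 and between 5.45 and 5.93 in TEL-JAK2, and those of mitosis genes between 11.13 and 11.36 in ICN1 and between 8.68 and 9.65 in TEL-JAK2.

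Genes induced by NOTCH1 in T-lineage cells were mostly lower in TEL-JAK2 where they differed. Heyl, a transcriptional repressor induced by NOTCH, was 19.8-fold lower (-4.30 ± 0.30), Nrarp, a feedback inhibitor of the pathway, 22.8-fold lower (-4.51 ± 0.67), and Hes5, another repressor, 2.01-fold lower (-1.01 ± 0.13). The TEL-JAK2 mean of Heyl, 4.36, was near background. Hes1 (-2.00 ± 0.58) and Myc (-1.16 ± 0.25), named after their values were seen, were lower as well. Hes1 lost its call without any 1 of the ICN1 arrays (adjusted p = 0.113, 0.0631 and 0.120) or without TEL-JAK2 replicates 1, 2 or 3 (0.109, 0.103 and 0.102). Lfng, a glycosyltransferase that modifies NOTCH receptors, was 5.0-fold higher (2.32 ± 0.23), and so was the chemokine receptor Ccr7 (2.02 ± 0.46). Of 19 members measured, 7 were lower, 2 higher and 10 not called, and 8 and 2 when adjusted over the list alone. The list was called lower with a median of -0.25 (camera adjusted p = 0.0302, and adjusted p = 0.372 with an estimated correlation). With CD3 centring 10 members were lower and 2 higher. The list call was lost without ICN1 replicate 2 (adjusted p = 0.0753) and with dim genes left out (0.0936). The receptor genes Notch1 (-0.19 ± 0.43) and Notch3 (-0.18 ± 0.44) were not called. Notch1 read 11.99, 12.61 and 11.40 in the ICN1 arrays and averaged 11.80 ± 0.72 (SD) in TEL-JAK2. Whether the mouse probe sets detect the ICN1 transcript is not given in the sources used here.

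Of 16 target genes of JAK-STAT5 signalling, 9 were higher in TEL-JAK2, 1 lower and 6 not called, and 10 and 1 when adjusted over the list alone. With CD3 centring 7 were higher and 4 lower. The feedback inhibitors Socs2 (48.8-fold, 5.61 ± 0.37), Socs3 (18.7-fold, 4.22 ± 0.26), Socs1 (12.5-fold, 3.64 ± 0.20) and Cish (9.28-fold, 3.21 ± 0.14) were all higher without overlap. Of 5 further probe sets of Socs2, 4 were called and 1 was not (adjusted p = 0.649). The kinase gene Pim1 (-0.05 ± 0.14) and the survival gene Bcl2l1 (-0.14 ± 0.39) were not called. Id1, an inhibitor of helix-loop-helix factors, was the 1 member lower (-2.26 ± 0.50), and lost its call without ICN1 replicate 2 (adjusted p = 0.0581). The camera test of the list gave an adjusted p = 0.000383, and adjusted p = 0.124 with an estimated correlation. That estimate was -0.0278, below the preset 0.01, so a higher correlation of the members is not what raised the p. The setting with an estimated correlation therefore changes more than the correlation. Jak2 itself averaged 9.80 ± 0.11 (SD) in TEL-JAK2 and 9.28 ± 0.57 (SD) in ICN1, a difference of 0.52 ± 0.25 that was not called (adjusted p = 0.179) and read -0.10 with CD3 centring. It was called from its other probe set (1.34 ± 0.25, adjusted p = 0.00830) and without ICN1 replicate 1 (adjusted p = 0.00816). Etv6, the mouse counterpart of TEL, differed by 0.55 ± 0.30 (adjusted p = 0.231, and 0.0478 without ICN1 replicate 1) and by -0.07 with CD3 centring. Whether these probe sets detect the fusion transcript is not given in the sources used here.

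**Figure D3:**
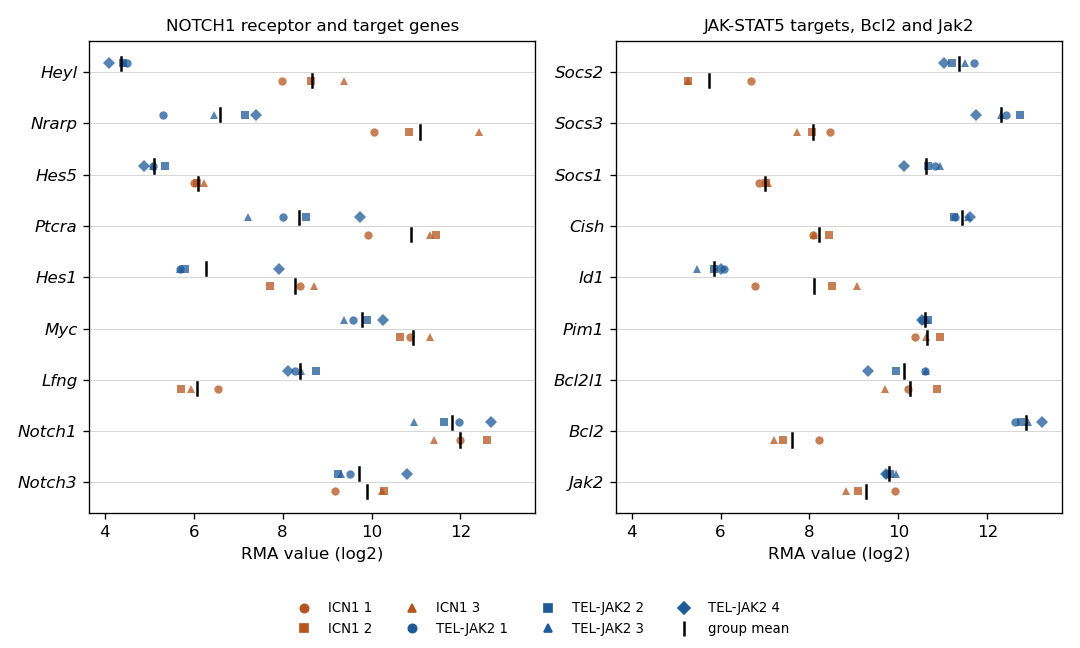
Points are RMA values (log2) of single arrays, by group and replicate, and black bars are group means, for NOTCH1 receptor and target genes (left) and for JAK-STAT5 targets, Bcl2 and Jak2 (right). Heyl averages 8.66 in ICN1 and 4.36 in TEL-JAK2, Socs2 averages 5.75 and 11.36, and Notch1 and Pim1 overlap between the groups.

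Among regulators of apoptosis, Bcl2, which blocks mitochondrial cell death, was 38.6-fold higher in TEL-JAK2 (5.27 ± 0.26), from 7.61 ± 0.53 (SD, n = 3) in ICN1 to 12.88 ± 0.26 (SD, n = 4). The BH3-only genes Bcl2l11 (1.78 ± 0.45) and Bmf (1.97 ± 0.41) and Mcl1 (0.93 ± 0.12) were higher too, the latter not called with CD3 centring (adjusted p = 0.0986). A further probe set of Bmf was called higher (1.43, adjusted p = 0.0131 by limma over all probe sets). Another, averaging 5.6, was not called (adjusted p = 0.969). Of 11 family members 5 were higher, 1 lower and 5 not called, and 5 and 1 when adjusted over the list alone. Bid, the 1 lower member (-1.08 ± 0.26), lost its call without ICN1 replicates 1 or 3 or TEL-JAK2 replicate 1 (adjusted p = 0.0504, 0.0696 and 0.0601). Of the 7 fits without 1 array, Bcl2l11 lost its call in 6, all but the one without ICN1 replicate 2 (adjusted p from 0.0518 to 0.0796), and Bad in 6, all but the one without TEL-JAK2 replicate 4 (0.0676 to 0.140). The members went both ways and the list was not called (camera adjusted p = 0.160). It was called with the mean of a gene's probe sets (0.0376) and by fry (adjusted p = 0.000439). With CD3 centring 3 members were higher and 4 lower, and 1 higher member, Bad, turned from 0.53 to -0.10. The p53 target list had 2 of 14 members higher, Ccng1 (0.99 ± 0.26) and Btg2 (1.09 ± 0.29), the same number when adjusted over the list alone. It was not called (adjusted p = 0.0905, but 0.0125 without TEL-JAK2 replicate 3). Each of these 2 genes lost its call without ICN1 replicate 3 (adjusted p = 0.0905 and 0.0636) and without TEL-JAK2 replicate 2 (0.0684 and 0.0717). Ccng1 lost it also without ICN1 replicates 1 or 2 or TEL-JAK2 replicate 4 (0.0568, 0.0711 and 0.0516), and Btg2 also without TEL-JAK2 replicates 1 or 3 (0.0879 and 0.0805). With CD3 centring 2 other p53 targets were lower and neither Ccng1 nor Btg2 was called (adjusted p = 0.256 and 0.0786).

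Genes of MHC class I antigen presentation were all higher in TEL-JAK2 with the deposited scaling, 10 of 10 measured, also when adjusted over the list alone, although with CD3 centring 5 of the 10 were not called and B2m turned from 0.40 to -0.22. B2m also lost its call without ICN1 replicates 1 or 3 or TEL-JAK2 replicates 1, 2 or 3 (adjusted p from 0.0716 to 0.0870). Nlrc5, the transactivator of these genes, was 15-fold higher (3.91 ± 0.54), the peptide transporter gene Tap1 3.19-fold (1.68 ± 0.26) and the immunoproteasome gene Psmb8 1.90-fold (0.92 ± 0.09, but not called with CD3 centring, adjusted p = 0.149). Dim probe sets of Tap1, averaging 3.55 and 3.12, read -0.03 and 0.0013 and were not called. A brighter one, averaging 5.80, was called higher (0.69, adjusted p = 0.0360 by limma over all probe sets). The list was called with an adjusted p = 1.17e-05 by camera, and adjusted p = 0.372 with an estimated correlation. The NF-kB list had 7 of 15 members higher and 8 not called, 10 higher when adjusted over the list alone, and 5 higher with CD3 centring. Examples were Ltb, a membrane-bound cytokine (3.30 ± 0.28), Nfkbie, an inhibitor induced by the pathway (1.85 ± 0.13), and Traf1, an adaptor of tumour necrosis factor receptors (2.69 ± 0.42). The list was called with an adjusted p = 5.96e-05, and adjusted p = 0.372 with an estimated correlation.

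T-cell identity genes also differed. Of 15 genes of the T cell receptor complex and its proximal signalling, 10 were higher in TEL-JAK2, 1 was lower and 4 were not called, and 12 and 3 when adjusted over the list alone. With CD3 centring 4 of the 10 were not called, 3 genes were lower and Cd3d and Zap70 turned to -0.11 and -0.03. The 4 were Cd3d, Cd3g, Cd247 and Zap70. Cd3d, Cd3g and Cd247 are centring genes, whose mean difference together with Cd3e is set to 0 by construction. Their lost calls therefore say nothing about these genes. Themis, needed for thymocyte selection (1.41 ± 0.15), the adhesion receptor Cd2 (1.26 ± 0.14), the kinase Prkcq (1.22 ± 0.15) and the adaptor Lat (1.11 ± 0.16) were higher. The 1 lower gene was Cd5 (-1.76 ± 0.49), whose call was lost without any 1 of the ICN1 arrays (adjusted p = 0.109, 0.0801 and 0.0837) or without TEL-JAK2 replicate 1 (0.0886). Camera called the list at an adjusted p = 0.000992, and adjusted p = 0.372 with an estimated correlation. Beside these genes, the erythroid list stood at 11.05 to 11.33 in ICN1 and at 5.45 to 5.93 in TEL-JAK2. Genes induced by T cell receptor signals went both ways, 3 of 17 higher, 2 lower and 12 not called, with the same counts when adjusted over the list alone. With CD3 centring 3 were higher and 7 lower. With the deposited scaling the list was not called by camera (adjusted p = 0.285) but was called higher by fry (adjusted p = 0.0133). The inhibitory receptor Ctla4 was 40.6-fold higher (5.34 ± 0.13) and the calcineurin target Nfatc1 2.77-fold (1.47 ± 0.25). Another probe set of Nfatc1, averaging 5.10, was not called (adjusted p = 0.239), while its remaining ones were called higher (0.47 to 0.84). Pdcd1 (2.72 ± 0.68) was higher, but lost its call without ICN1 replicate 2 or TEL-JAK2 replicates 1 or 2 (adjusted p = 0.0639, 0.0550 and 0.0515). Rcan1 was lower (-1.20 ± 0.17) beside Cd5, and Il2 (-0.01 ± 0.14) and Egr2 (-0.17 ± 0.61) were not called.

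Markers of thymocyte stages were distributed unequally. Double-negative thymocyte genes were lower in TEL-JAK2 for 5 of 13 members, Lyl1, Nrarp, Cd44, Ptcra and Hes1, and not called for 8, and 7 were lower when adjusted over the list alone. The list was called at an adjusted p = 0.0196, and adjusted p = 0.450 with an estimated correlation, and lost its call with dim genes left out (0.0535). This list shares 7 genes with the NOTCH1 targets, among them Nrarp, Ptcra and Hes1. Lyl1 is also expressed in erythroid cells or early marrow progenitors, and the ICN1 samples were marrow cells. A difference in thymocyte stage therefore cannot be told apart from one of tissue. Ptcra, the pre-T cell receptor chain (-2.52 ± 0.62), lost its call without ICN1 replicates 2 or 3 (adjusted p = 0.0827 and 0.0746) or TEL-JAK2 replicates 1 or 2 (0.0676 and 0.0539). Cd44 (-2.86 ± 0.66) lost its call without ICN1 replicate 3 or TEL-JAK2 replicate 1 (0.0622 and 0.0543). A dim probe set of Cd44, with a mean of 3.34, read 0.08, and its brighter further probe sets read -2.60 and -2.72. Double-positive thymocyte genes were higher for 6 of 13 members, among them Arpp21 (1.44 ± 0.24), and not called for 7, including the coreceptor Cd4 (0.29 ± 0.54). When adjusted over the list alone 7 were higher, and the list had an adjusted p = 0.0196, and adjusted p = 0.488 with an estimated correlation. The coreceptor gene Cd8b1 was 3.42-fold higher (1.77 ± 0.43), a call lost without TEL-JAK2 replicates 1, 2 or 3 (adjusted p = 0.0618, 0.0569 and 0.0608). Mature single-positive T cell genes were higher for 4 of 9 members, Itgb7 (2.72 ± 0.31), H2-K1 (1.45 ± 0.28), Cd27 (0.88 ± 0.19) and Ccr7, and for 5 when adjusted over the list alone. Its mean level was 9.31, 10.71, 9.24 and 10.69 in TEL-JAK2 replicates 1 to 4, and 9.18, 8.36 and 9.28 in ICN1, so the groups overlapped. That list was called at an adjusted p = 0.0301, and adjusted p = 0.450 with an estimated correlation. Its call was lost without ICN1 replicate 2 (adjusted p = 0.0688) or TEL-JAK2 replicate 4 (0.0959) and with dim genes left out (0.0535). With CD3 centring 8 double-negative genes were lower, 6 double-positive genes higher and 2 lower, and 3 mature genes higher. Cd27 lost its call without ICN1 replicate 2 as well (adjusted p = 0.0520) and with CD3 centring (0.234).

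Of 19 transcription factors and suppressors altered in human T-cell leukemia, 3 were lower in TEL-JAK2, 1 was higher and 15 were not called, with the same counts when adjusted over the list alone. With CD3 centring 12 were lower and 1 higher. The list was not called by camera (adjusted p = 0.274) but was called lower by fry (adjusted p = 1.58e-05). Tal1 (-6.35 ± 0.10), Lmo2 (-4.48 ± 0.44) and Lyl1 (-2.68 ± 0.22), which are also expressed in erythroid cells or early marrow progenitors, were lower together with the erythroid markers, at 10.19, 11.35 and 9.30 in ICN1 and 3.85, 6.87 and 6.62 in TEL-JAK2. Bcl11b, which commits progenitors to the T lineage, was 3.08-fold higher (1.62 ± 0.15). Mef2c (0.06 ± 0.32) and Hhex (-0.03 ± 0.39) were not called.

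Cytotoxic effector genes were higher in TEL-JAK2 for 5 of 17 members and not called for 12, with the same count when adjusted over the list alone. The mean level of the list was 6.54, 8.88, 6.21 and 8.23 in TEL-JAK2 replicates 1 to 4, against 5.19 to 5.69 in ICN1. Camera gave an adjusted p = 0.000425, and adjusted p = 0.450 with an estimated correlation. The protease gene Ctsw was 21.6-fold higher (4.43 ± 0.37), Nkg7, a protein of cytotoxic granules, 29.8-fold (4.90 ± 0.66) and the granzyme gene Gzma 4.53-fold (2.18 ± 0.35). The others were Ccl4 (0.87 ± 0.24) and Il2rb (3.15 ± 0.84). Ccl4 lost its call in 6 of the 7 fits without 1 array, all but the fit without TEL-JAK2 replicate 1 (adjusted p from 0.0507 to 0.109), and with CD3 centring (0.432), where 4 cytotoxic genes were higher. Il2rb lost it without ICN1 replicates 2 or 3 or TEL-JAK2 replicates 1, 2 or 4 (adjusted p from 0.0554 to 0.107). The natural killer cell receptors Klrc1 (0.09 ± 0.20) and Ncr1 (0.23 ± 0.14) were not called. Chemokine receptors and adhesion molecules were higher for 7 of 15 members, lower for 3 and not called for 5, with the same 7 and 3 when adjusted over the list alone. With CD3 centring 6 were higher and 3 lower. The homing list had an adjusted p = 0.0231, and adjusted p = 0.372 with an estimated correlation. Cxcr4 (-0.82 ± 0.23), Itga4 (-2.51 ± 0.73) and Cd44 were the lower ones. Cxcr4 lost its call without ICN1 replicates 2 or 3 or TEL-JAK2 replicates 1, 2 or 4 (adjusted p from 0.0539 to 0.0945). Itga4 lost it in 6 of the 7 fits without 1 array, all but the fit without TEL-JAK2 replicate 2 (adjusted p from 0.0537 to 0.111), and its 4 other probe sets were not called. The integrin Itgae, which binds E-cadherin on epithelial cells, was 36.0-fold higher (5.17 ± 0.49), the selectin ligand Selplg 4.76-fold (2.25 ± 0.27) and Ccr4 6.35-fold (2.67 ± 0.48), while the egress receptor S1pr1 was not called (-0.14 ± 1.08).

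Most genes of cell division were lower in TEL-JAK2. All 16 measured genes of G2 and mitosis were lower, also when adjusted over the list alone, with differences from -2.29 to -1.20. The list had an adjusted p = 1.06e-12 by camera, and adjusted p = 0.372 with an estimated correlation. Examples were the mitotic kinases Aurka (4.04-fold, -2.01 ± 0.17) and Plk1 (3.06-fold, -1.61 ± 0.18) and the kinetochore gene Cenpf (4.89-fold, -2.29 ± 0.24). Dim second probe sets of Aurka and Top2a, averaging 3.86 and 4.10, were not called (adjusted p = 0.518 and 0.243, the latter at 0.22). A further one of Top2a, averaging 8.88, was called at -2.57 (adjusted p = 0.00206). DNA replication genes were lower for 16 of 17 members, again the same count when adjusted over the list alone. The initiation factor Cdc6 differed by -2.44 ± 0.34, Gins1 by -1.73 ± 0.21 and the ribonucleotide reductase gene Rrm1 by -1.79 ± 0.25, while Cdca7 was not called (0.56 ± 0.25, and called at an adjusted p = 0.0420 without TEL-JAK2 replicate 4). Its camera test gave an adjusted p = 5.68e-09, and adjusted p = 0.372 with an estimated correlation. Ribosome biogenesis and MYC-responsive genes were lower for 13 of 16 members, for 14 when adjusted over the list alone and for 16 with CD3 centring. Odc1, the first enzyme of polyamine synthesis, differed by -1.92 ± 0.12 and Cad, of pyrimidine synthesis, by -1.89 ± 0.27. A dimmer probe set of Cad, averaging 5.7, was not called (adjusted p = 0.0638 by limma over all probe sets). Another was called lower (-1.35, adjusted p = 0.0211). This list had an adjusted p = 2.63e-08, and adjusted p = 0.372 with an estimated correlation. The arrays with high values of these lists also held the erythroid transcripts, whose list level was 11.05 to 11.33 in ICN1 and 5.45 to 5.93 in TEL-JAK2.

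None of the 3 lists of metabolic and stress genes was called with all 7 arrays and the deposited scaling. Cholesterol synthesis genes were higher for 6 of 16 members and not called for 10, with the same count when adjusted over the list alone. They were led by Mvd (1.95 ± 0.25) and Dhcr7 (1.54 ± 0.30), and 3 of the 6, Lss, Sc5d and Mvk, turned to -0.12, -0.03 and -0.04 with CD3 centring, where 2 members were higher and 8 lower. Lss also lost its call without ICN1 replicates 2 or 3 or TEL-JAK2 replicates 1, 3 or 4 (adjusted p from 0.0662 to 0.0991). Further probe sets of Lss (adjusted p = 0.457 and 0.272 by limma over all probe sets) and Sc5d (0.761 and 0.54) were not called. The list was not called (adjusted p = 0.285), and its median (-0.02) and mean (0.26) had opposite signs. Glycolysis genes had 1 of 15 members lower, the glucose transporter Slc2a3 (-3.02 ± 0.86), 0 when adjusted over the list alone and 9 with CD3 centring. The list was not called (adjusted p = 0.113, but 0.0486 without TEL-JAK2 replicate 2 and 0.0490 without TEL-JAK2 replicate 4). Slc2a3 lost its call in 6 of the 7 fits without 1 array, all but the fit without TEL-JAK2 replicate 4, with adjusted p from 0.0585 to 0.102. Immediate early and heat shock genes, which also move with tissue handling, had 2 of 14 members higher, Jund (0.77 ± 0.16, but not called from another probe set, adjusted p = 0.958) and Dusp1 (0.78 ± 0.22), and 1 when adjusted over the list alone. That list was not called (adjusted p = 0.709). Dusp1 lost its call in 6 of the 7 fits without 1 array, all but the fit without ICN1 replicate 2, with adjusted p from 0.0514 to 0.124. With CD3 centring 6 members were lower and neither Jund nor Dusp1 was called (adjusted p = 0.479 and 0.565).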

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

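The tests of cells of the marrow, of background in Y-linked probe sets and of RNA of both sexes were chosen after the results were seen. Among the 4 TEL-JAK2 arrays, a named gene is listed here when its highest or lowest array lay further from the nearest other array, relative to the range of the 4, than Dixon's critical value. This held for 19 of 198 named genes. Chance gives about 1 in 20 groups, so about 10 of 198 would be listed by chance, and the 3 ICN1 arrays were not tested in this way.

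TEL-JAK2 replicate 4 stood apart in 13 of the 19 genes. Of the sex-linked genes, Xist read 5.19 there and 13.12 to 13.36 in the other 3 arrays, Eif2s3y 10.23 against 3.18 to 3.29, Kdm5d 7.60 against 3.07 to 3.42 and Uty 6.55 against 3.95 to 4.30. This array was therefore the single one of the 7 with Y-linked transcripts and a low Xist value. Genes of stroma were higher in it as well, with Sparc at 9.29 (5.83 to 6.39 in the others), Col1a2 at 8.76 (5.85 to 6.28), Dcn at 8.87 (6.38 to 6.75) and Pdgfra at 5.58 (4.20 to 4.33). Hes1 at 7.92 (5.68 to 5.81) and Pdcd1 at 10.30 (8.69 to 8.82) were higher, whereas Ccr9 at 9.91 (12.11 to 12.45), Ccr4 at 7.58 (8.79 to 8.84) and Ltb at 12.06 (13.05 to 13.15) were lower. The source of these differences was not tested.

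In TEL-JAK2 replicate 3, Flt3 read 6.34 (6.998 to 7.056 in the others), Ccl25 5.85 (6.26 to 6.33) and Pa2g4 9.74 (10.15 to 10.22), and Gp9 was higher at 6.74 (6.33 to 6.39). In TEL-JAK2 replicate 1, Cr2 was higher at 5.10 (4.52 to 4.56), and in TEL-JAK2 replicate 2 H2-K1 was higher at 14.01 (13.65 to 13.68). In these 6 genes the 4 arrays spanned less than 1 log2.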

How the results depend on the processing

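The settings that centre the arrays on CD3 genes and that leave out ICN1 replicates 1 and 2 together were chosen after seeing the data. The number of called genes, 4380, depended on the feature tested and on the test. Testing all probe sets, which are more features, gave 7865 (3704 higher, 4161 lower, 3676 at least 2-fold apart). A test against a 1.5-fold difference, a stricter hypothesis, gave 1187 (515, 672 and 1180), and a stricter adjusted p under 0.01 gave 2191 (987 higher, 1204 lower). The per-gene test with unequal variances, which does not pool the spread over genes, gave 1632 (744, 888 and 991), and 1598 of these were among the 4380. With ICN1 replicates 1 and 2 left out, which leaves 1 ICN1 array assumed to vary like the TEL-JAK2 arrays, 2596 were called (1039 higher), 2095 of them among the 4380. The remaining settings of the gene test called 4210 to 4648 genes, and the fits without 1 array 3209 to 4236.

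Centring on CD3 genes changed the number of called genes most. It called 12197 genes (787 higher, 11410 lower, 3683 at least 2-fold apart), 2989 of them among the 4380. It lowered every difference by the same 0.62, because the CD3 genes averaged 11.74 in ICN1 and 12.36 in TEL-JAK2. That constant shift turned small positive differences negative: B2m -0.22, Bad -0.10, Foxn1 -0.29, Gata2 -0.62, Hspa1a -0.59, Lss -0.12, Nsdhl -0.58, Pax5 -0.60, Psmb11 -0.58 and Sc5d -0.025. Of 198 named genes, 113 were called in both scalings with the same direction, 16 lost their call, 22 gained one and 47 were called in neither. The sign changed in 5 of the 16, 5 of the 22 and 25 of the 47. Calls were gained also by genes near background in both groups. Examples were Il2 (3.91 in ICN1 and 3.89 in TEL-JAK2) and Hba-a1 (3.91 and 3.87), at -0.63 and -0.66 with this centring. Such calls follow from the constant shift and show no difference in these genes. Which of the 2 scalings is nearer to the RNA content of the cells was not tested.

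Of the 19 lists called with the preset correlation, 1 was called with an estimated correlation. The JAK-STAT5 list then had an adjusted p = 0.124 and the NOTCH1 list 0.372. The estimated correlation was -0.0278 for the JAK-STAT5 list, below the preset 0.01, and 0.0537 for the NOTCH1 list. The unadjusted camera p of the JAK-STAT5 list rose from 9.24e-05 to 0.00854 without a higher correlation. Calls lost in this setting can therefore not be put down to correlation alone. The NOTCH1 list also lost its call with dim genes left out (adjusted p = 0.0936) and without ICN1 replicates 1 and 2 (0.105), while camera placed it on the higher side of the other genes with CD3 centring (0.807). That placement is no change of the genes, since list and other genes moved by the same amount, and 10 members were then lower and 2 higher. List tests with this centring are not interpreted. Over the fits without 1 array its adjusted p ranged from 0.00386 to 0.0753, the latter without ICN1 replicate 2. Fry called 19 lists, 4 of them not called by camera. These were the BCL2 family (adjusted p = 0.000439), the T-cell leukemia factors (1.58e-05), the genes induced by T cell receptor signals (0.0133) and thymic epithelium (0.00971). Fry did not call 4 lists that camera called, among them granulocytes (0.054), macrophages (0.0815) and dendritic cells (0.135). Camera on ranks added stroma (adjusted p = 0.048).

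Other probe sets had the opposite sign for Axl (0.0173), Cd44 (0.0834), Gp1bb (-2.36), Tap1 (-0.0338) and Top2a (0.22), for which the cause was not tested. That of Gp1bb, averaging 4.78, was called (adjusted p = 0.0409 by limma over all probe sets), while its brightest probe set was not (0.25). Those of Axl, Cd44, Tap1 and Top2a were dim, with means of 3.12, 3.34, 3.55 and 4.10, and weigh little against the calls. Brighter further probe sets of Cd44 (-2.60 and -2.72), Tap1 (0.69) and Top2a (-2.57) had the sign of the call. Xist ranged from -1.27 to 1.45 over the fits without 1 array, and was called higher without TEL-JAK2 replicate 4, where Xist read 5.19 (adjusted p = 0.00234). Of 129 called named genes, 91 were called in all 7 fits without 1 array, as were 16 of 19 lists. Median centring and cyclic loess each changed 2 of 198 named genes, by ending their call. The offset planned for untransformed values was not run, since the values are on the log2 scale.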

Other observations

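The tests of cells of the marrow, of background in Y-linked probe sets and of RNA of both sexes were chosen after the results were seen, as were the settings of CD3 centring and of leaving out ICN1 replicates 1 and 2. The cytotoxic list varied within TEL-JAK2, with mean levels of 6.54, 8.88, 6.21 and 8.23 in replicates 1 to 4, against 5.69, 5.19 and 5.33 in ICN1. Lists of monocyte and macrophage genes (6.94, 8.32, 6.23 and 8.43), mature single-positive genes (9.31, 10.71, 9.24 and 10.69) and genes induced by T cell receptor signals (7.02, 8.10, 6.92 and 7.89) were also higher in TEL-JAK2 replicates 2 and 4 than in 1 and 3. The same order held, among others, for NOTCH1 targets (7.72, 7.90, 7.52 and 8.42), double-negative genes (7.63, 8.01, 7.14 and 8.80), MHC class I (12.07, 12.58, 11.95 and 12.21) and homing (8.96, 9.81, 8.71 and 9.44). Gzmb, named after its values were seen, read 6.51, 13.28, 5.67 and 12.41 in the TEL-JAK2 arrays, and Ifng, named in the same way, 3.70, 10.24, 3.71 and 7.98. The cause of this spread was not tested.

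Camera called 0 of 20 chromosomes, and 0 had an unadjusted p under 0.05. The chromosomes held 458 to 1443 genes, and the preset correlation of 0.01 widens the variance most in large sets. The test could therefore hardly call a chromosome and does not exclude gains. Per array, the median deviation of a chromosome's genes from the mean of the 7 arrays ranged from -0.0626 to 0.0491 log2. The smallest p was 0.567, for chromosome 17, and 34 of 35 splits of the 7 arrays gave one as small, and the smallest p of any other split was 0.135, so chance cannot be excluded.

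For the count of called genes, 1 of 35 splits, the real one, gave as many as 4380 and the highest other split gave 3. That share, 0.0286, is the smallest that 35 splits can give. Every other split mixed the groups, so a difference between the groups itself lowered its calls. Chance is therefore argued against only to that share. The count of genes at least 2-fold apart was 2078, also reached in 1 of 35 splits, with 3 as the highest other. For the number of called lists chance cannot be excluded, because 2 of 35 splits gave 19 or more, and the highest other gave 19. A split that exchanges 1 array per group keeps part of the group difference, and can call lists through it. These counts, and those of single lists, therefore do not show that chance gave the lists either. Counted for single lists, 1 of 35 splits had as small a p for JAK-STAT5 targets, T cell receptor signalling and erythroid genes, 2 for mitosis and DNA replication, 3 for MHC class I, NF-kB and ribosome biogenesis, and 8 for NOTCH1 targets. The number was 7 for megakaryocyte genes, 9 for homing, 10 for mature single-positive genes, 11 for double-negative genes, 12 for cytotoxic genes, 13 for granulocyte genes, 14 for double-positive and macrophage genes and 15 for dendritic genes.

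Most genes of mitosis and DNA replication were lower in TEL-JAK2. All 32 members called lower kept their call in each of 4 other scalings, but this does not decide whether array scaling contributes. CD3 centring lowers every difference, and the other 3 scalings raised the members by a median of at most 0.0248 log2, against a smallest difference of 0.67. Dividing erythroid and other marrow cells in the ICN1 samples may contribute, but the erythroid level ranged over 0.277 log2 in the 3 ICN1 arrays, too little to show whether the mitosis level follows it. Genotype and tissue cannot be told apart in this design and stay open, both untested.

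ICN1 replicates 1 and 2 held both Xist and Y-linked transcripts. Xist read 11.51 and 11.79, Eif2s3y 8.93 and 9.41, Kdm5d 7.73 and 7.99 and Uty 5.53 and 5.69, against 12.09, 3.25, 2.64 and 4.10 in ICN1 replicate 3. Background in the Y-linked probe sets is argued against, since for the brightest probe set of Eif2s3y, Kdm5d and Uty the smallest excess over the highest of the arrays with low Y-linked values was 1.23 log2. RNA of animals of both sexes in 1 sample is a candidate explanation, which stays open because 1 of 2 other Xist probe sets lay over 2 log2 above TEL-JAK2 replicate 4, the array with the lowest Xist value, in both ICN1 arrays. That probe set read 8.45 and 9.38 against 3.06. The other read 6.119 and 6.386 against 4.125, just short of the cut in ICN1 replicate 1 and over it in ICN1 replicate 2. The brightest probe set read 11.51 and 11.79 against 5.19. All Xist probe sets thus lay above TEL-JAK2 replicate 4 in both arrays, so the cut, not an absence of Xist, leaves the explanation open.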
